A study of Mus musculus with 8 samples.

How the data were processed

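Renal artery tissue was digested with collagenase and CD34+/CD105- cells were sorted by flow cytometry, per the labels' protocols. RNA was isolated with a mirVana kit and measured on a 7900HT Fast real-time PCR system with FAM-labelled probes, per the labels' protocols. The deposited tables hold Ct values, delta Ct values and fold changes for 8 samples, 4 after sham surgery and 4 after bilateral renal ischemia/reperfusion. The labels number separate mice, so each sample was taken as 1 biological replicate. The instrument software, the card type and the reference RNA are not given in the sources used here.

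The deposited Ct table has 769 assay rows for 757 distinct assays, of which 750 are miRNA assays and 7 are controls. The catalogue numbers fall into 2 series, taken here as 2 cards with 375 miRNA assays each. In the deposited delta Ct table, each value was the Ct minus a single reference value per sample and card, which held for every well with a Ct within 7.11e-15 cycles. The authors computed the deposited fold change as a ratio, 2 to the power of the mean sham delta Ct minus the mean experimental delta Ct, per the file headers. Recomputing this fold from the deposited delta Ct values matched within a relative difference of 0.000246. In 13 wells, the deposited delta Ct table held a value where the Ct table had none, equal to Ct 0 minus the reference, and these wells were treated here as missing.

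The sign of delta Ct was turned, so that higher values mean more RNA on the log2 scale, 1 unit being a doubling if PCR is fully efficient. An assay counted as detected below Ct 35, and a miRNA was tested if detected in at least 3 samples of each group. Values not detected were missing, repeated wells of an assay were averaged, and control assays were not tested. This left 72 miRNAs. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at 0.05. Detection was compared with Fisher's exact test, and single values per sample with exact two-sided permutation tests over 70 assignments. No number of wells per value is given in the sources used here, so precision rests on the spread between mice.

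The 14 miRNA lists were fixed from general knowledge. They cover hypoxia, kidney ischemia/reperfusion, endothelium, the miR-17-92 clusters, let-7, p53, the Dlk1-Dio3 cluster, and markers of leukocytes, erythroid cells, smooth muscle, striated muscle, fibroblasts, epithelium and neural cells. Lists with at least 3 tested members were tested with limma's camera statistic on the moderated limma values, with a preset correlation of 0.01, and again with a correlation estimated per list. fry was run on miRNAs with no missing value. The main tests, the lists and the naming rule were set before the data were examined, as were the alternatives not described as chosen later. The rule names miRNAs past the threshold, or else the 24 with the smallest p, the 4 members of each list with the smallest p, 8 preset miRNAs, all controls, assays detected in all mice of 1 group and none of the other, and the 3 miRNAs with the lowest mean Ct over all samples, taken here among those detected in all 8. Any other miRNA named was chosen after its values were seen.

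The fit was tested on simulated data with the real spread and missing values of the 72 miRNAs in this comparison. It called 29.7% of changes of 2 log2 units, 61.7% of 3, 75.7% of 4 and 90.7% of 6, with a mean false discovery share of 4.36%. Each simulation changed 6 miRNAs at every one of these sizes together, with noise independent between miRNAs. The rates hold for that share of changed miRNAs and can be lower where fewer change. Alternatives were other references, detection limits, treatments of missing values, moderation, a block by mouse number, an exact test and leaving out each mouse. Gene neighbours were taken from RefSeq on GRCm38.p6, where 63 of the 72 assays matched a miRNA gene by name.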

Results

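MicroRNAs were profiled by real-time PCR in CD34+/CD105- cells sorted from the mouse renal artery. CD34 is a surface marker of endothelial and progenitor cells, and CD105 (endoglin) is a surface marker of endothelial and mesenchymal stromal cells. The cells came from 4 mice after sham surgery and 4 mice after clamping of both renal arteries followed by reperfusion, and the comparison asks which miRNAs differ in these cells after renal ischemia/reperfusion. Each sample was measured with 750 distinct miRNA assays and 7 control assays. The readout is the threshold cycle (Ct), which is lower where more RNA is present. Of the 750 miRNA assays, 187 were detected below Ct 35 in at least 1 sample, 54 were detected in all 8 samples and 563 in none.

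The number of detected miRNA assays was 127, 75, 142 and 163 in sham mice 1 to 4, and 98, 82, 91 and 88 in ischemia/reperfusion mice 1 to 4. The sham mean was 127 ± 37.5 (SD, n = 4) and the ischemia/reperfusion mean was 89.75 ± 6.65 (SD, n = 4). The difference of -37 assays did not pass an exact two-sided permutation test (p = 0.143; the smallest p that 4 against 4 samples allow is 0.0286). Sham mouse 2 had the fewest detected assays of all samples. Without sham mouse 2 the difference was -54.25 assays (exact permutation p = 0.0286). Leaving out the lowest sham count widens the difference by construction, so this p is not a separate test of it. Without sham mouse 4, the highest count, the difference was -24.9 assays.

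**Figure D1:**
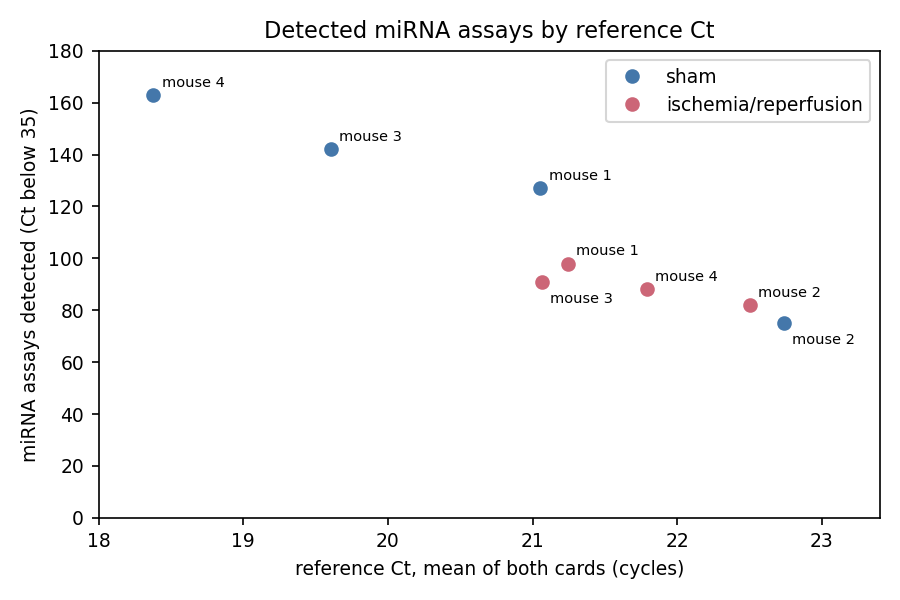
Number of miRNA assays detected below Ct 35 (vertical axis) against the mean reference Ct of both cards in cycles (horizontal axis), with 1 point per mouse coloured by group. Sham mouse 4, with the lowest reference Ct, had 163 detected assays, and sham mouse 2, with the highest, had 75.

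After ischemia/reperfusion, the miRNAs with the smallest p were lower than in sham mice, but none passed the adjusted threshold. The mmu-miR-214 assay, for a miRNA abundant in fibroblasts and other mesenchymal cells, had a log2 difference of -3.95 ± 1.17 (SE; 3 sham and 4 ischemia/reperfusion values). Sham mouse 2 had no Ct for it, and with Ct 35 in that well the log2 difference was -2.54 ± 1.57 (SE), with an unadjusted limma p of 0.140. miR-199a-3p, which is encoded next to miR-214, had a log2 difference of -2.65 ± 0.92 (SE, n = 4 per group). The endothelial miRNA miR-126-3p was at -1.59 ± 0.57, miR-218 at -1.89 ± 0.66, and miR-222 at -2.12 ± 0.74 (SE, n = 4 per group). Of the 72 miRNAs tested, 49 were lower and 23 were higher after ischemia/reperfusion against the deposited reference.

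By limma with Benjamini-Hochberg adjustment, 0 of the 72 miRNAs passed 0.05, and the lowest adjusted p was 0.228. At an unadjusted p under 0.05, limma gave 10 miRNAs, of which 10 were lower and 0 higher against the deposited reference. An exact permutation test per miRNA with the same adjustment gave 0, with 2 miRNAs, miR-218 and miR-126-3p, at an unadjusted p under 0.05. The smallest p this test allows is 0.0286, so over 72 miRNAs it could pass only if many reached that p together. Its count of 0 therefore adds little to the limma result. In all 4 ischemia/reperfusion mice, miR-218 and miR-126-3p lay below the sham mean, as did miR-222, miR-320, miR-145 and let-7c among others. Leaving out a single mouse produced a call in 2 cases. miR-199a-3p passed without sham mouse 2 (log2 difference -3.57, limma adjusted p = 0.0144), and miR-1896 passed without sham mouse 1 (log2 difference -12.02, limma adjusted p = 0.000793). The miR-1896 call rests on 2 sham values, 0.27 and -1.06 on the minus delta Ct scale, because sham mouse 4 was over the detection limit at Ct 35.5. Sham mouse 1, at -13.20, was as low as the ischemia/reperfusion mice, between -12.99 and -11.80. With values not detected set to Ct 35, miR-1896 was at -5.11 ± 3.53 (SE, n = 4 per group), with an unadjusted limma p of 0.182.

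The median log2 difference of the 72 miRNAs was -0.80 against the deposited reference, -0.24 against the mean of the miRNAs detected in all samples, and -1.93 without normalization. Against the mean of the miRNAs detected in all samples, 41 were lower and 31 higher, and 6 of the 8 with an unadjusted limma p under 0.05 were lower. Without normalization, 65 were lower and 7 higher, and 21 of 21 were lower. The differences below are against the deposited reference, so a miRNA near -0.80 lay at the centre of the tested miRNAs.

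The other miRNAs with an unadjusted p under 0.05 were miR-484 (-2.39 ± 0.80, 3 values per group), rno-miR-664 (-3.54 ± 1.28), miR-320 (-1.99 ± 0.78), miR-145 (-2.09 ± 0.84) and hsa-miR-196a (-2.10 ± 0.85, 3 values per group). With values not detected set to Ct 35, miR-484 was at -1.81 and hsa-miR-196a at -1.68, with an unadjusted limma p of 0.123 and 0.0658. The next lower miRNAs in order of p were miR-1896 (-7.75 ± 3.37), miR-21 (-2.99 ± 1.33), miR-127 (-1.75 ± 0.82), miR-99b (-2.83 ± 1.40) and miR-16 (-1.60 ± 0.82). miR-26b (-2.98 ± 1.70), miR-26a (-1.11 ± 0.65), miR-100 (-1.99 ± 1.22), miR-125a-5p (-1.13 ± 0.70), miR-191 (-1.06 ± 0.70) and miR-2146 (-1.15 ± 0.76) followed. Without ischemia/reperfusion mouse 3, miR-26b was at -1.02 and miR-99b at -1.80. Without ischemia/reperfusion mouse 4, miR-16 was at -0.86. With values not detected set to Ct 35, miR-99b was at -1.47 ± 1.68, miR-100 at -0.79 ± 1.48, miR-125a-5p at -2.04 ± 1.00 and miR-2146 at -2.10 ± 1.06 (SE, n = 4 per group). With undetermined wells at Ct 40, miR-100 turned to 0.46. Higher mean values after ischemia/reperfusion among the 24 miRNAs with the smallest p were those of miR-1894-3p (5.38 ± 2.87), hsa-miR-378 (1.41 ± 0.89) and miR-25 (1.14 ± 0.76). For miR-1894-3p, 2 of 3 ischemia/reperfusion values lay above the sham mean, and mouse 2 was left out at Ct 35.8. With Ct 35 in that well the log2 difference was 1.89 ± 3.85, and the authors' deposited table, which keeps the well, gives a fold of 3.25 against 41.7 here. Errors are standard errors of the log2 difference from 3 or 4 values per group, and the limma adjusted p of these miRNAs lay between 0.228 and 0.510.

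**Figure D2:**
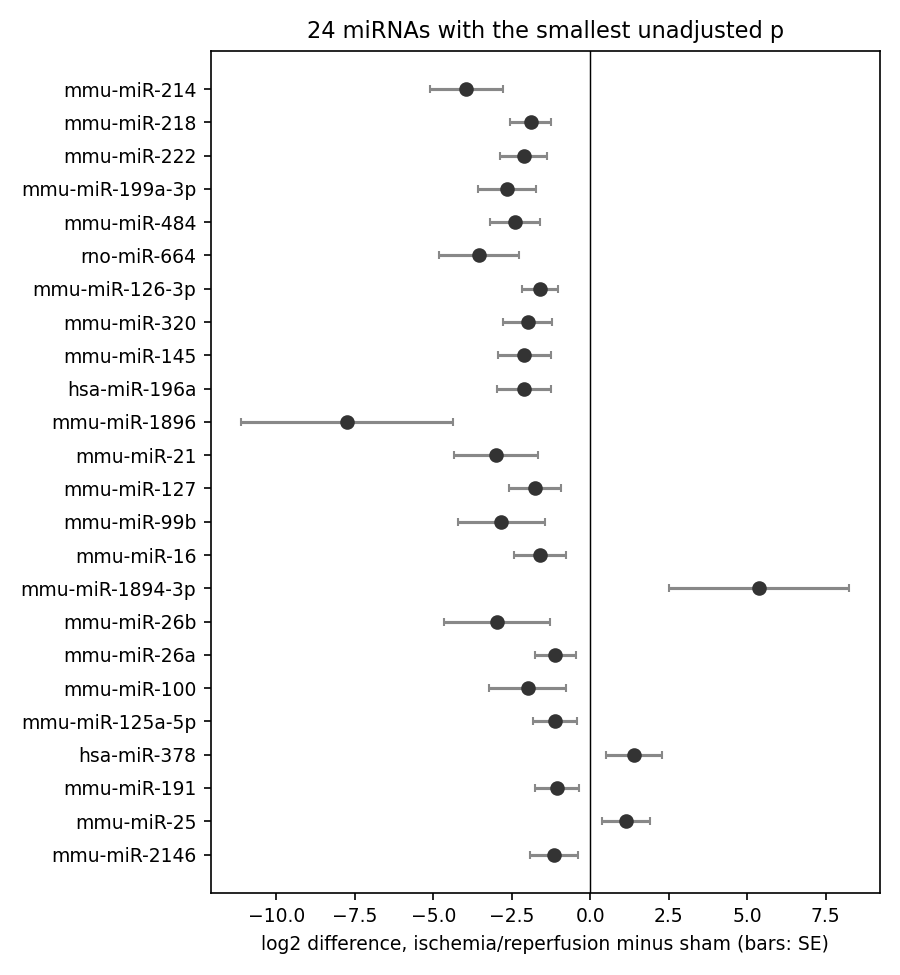
Log2 difference, ischemia/reperfusion minus sham (horizontal axis), of the 24 miRNAs with the smallest unadjusted p, with bars of 1 standard error. The mmu-miR-214 assay lies at -3.95, and miR-1896 and miR-1894-3p have standard errors of 3.37 and 2.87.

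Among fibroblast and mesenchymal markers, 6 of 6 tested members had lower mean values after ischemia/reperfusion, with a median log2 difference of -2.16. They included the mmu-miR-214 assay, miR-199a-3p, miR-21 (-2.99 ± 1.33) and miR-152 (-1.67 ± 1.33). When each mouse was left out, miR-152 ranged from -2.28 to -0.23, the latter without ischemia/reperfusion mouse 4. The list did not pass the threshold (limma camera adjusted p = 0.236, unadjusted p = 0.0331), and 0 members passed when adjusted over all miRNAs or adjusted over the list alone. With an estimated correlation the adjusted p was 0.826 and the unadjusted p 0.107. A second assay for miR-214, hsa-miR-214 on the other card, chosen after its values were seen, gave a log2 difference of -0.86 ± 0.87 (SE, n = 4 per group). That value includes sham mouse 2, at -7.85 the lowest sham value, which the mmu-miR-214 assay lacks. The difference between the assays was not tested, and their sequences were not compared.

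The miRNAs listed for kidney ischemia/reperfusion come from whole-kidney literature, and the list gives no expected direction. Of that list, 10 of 12 tested members were lower, beside 49 of all 72 tested miRNAs. The median log2 difference of the list was -1.35, with a camera adjusted p of 0.236. Its members with the smallest p were the mmu-miR-214 assay, miR-199a-3p, miR-126-3p and miR-21. Of the endothelial and angiogenic miRNAs, 7 of 10 were lower, with a median of -0.58 (camera adjusted p = 0.804), led by miR-218, miR-222, miR-126-3p and miR-100. The partner arm miR-126-5p, chosen after its values were seen, had a log2 difference of 0.11 ± 0.60 (SE, n = 4 per group), beside -1.59 ± 0.57 for miR-126-3p. Of the hypoxia-responsive miRNAs, 4 of 5 were lower, with a median of -1.11 (camera adjusted p = 0.630), and miR-24 was at -0.81 ± 0.57. The hypoxia-induced miR-210 had no Ct in any of the 8 samples.

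The miR-17-92 cluster and its paralogs had higher mean values for 3 of 5 tested members, with a median log2 difference of 0.90 (camera adjusted p = 0.236). The median was 0.24, with 3 of 6 members lower, when values not detected were set to Ct 35. That setting added only miR-20a, detected in 3 of 4 sham and 2 of 4 ischemia/reperfusion mice, which entered through the sham group alone. miR-25 (1.14 ± 0.76), miR-363 (1.24 ± 1.14) and miR-106b (0.90 ± 1.05) were higher against the deposited reference and lower without normalization, at -0.25, -0.15 and -0.49. miR-92a was at -0.93 ± 0.71. The let-7 family was lower in 3 of 3 tested members, let-7b (-0.34 ± 0.66), let-7c (-0.59 ± 0.56) and let-7d (-0.95 ± 1.05; -1.51 with Ct 35 for values not detected), with a camera adjusted p of 0.909. Of the p53- and apoptosis-linked miRNAs, miR-16, miR-195 (-1.24 ± 0.97) and miR-29a (-0.36 ± 0.68) were lower (3 of 3 tested, camera adjusted p = 0.743). miR-195 was at -0.35 without ischemia/reperfusion mouse 3, and miR-16 at -0.86 without ischemia/reperfusion mouse 4. Of the Dlk1-Dio3 imprinted cluster, miR-127 and miR-411 (-1.50 ± 1.53) were lower and miR-673 (1.07 ± 2.57) was higher, with a camera adjusted p of 0.909. miR-127 had no Ct in sham mouse 2 and turned to 0.21 with Ct 35 in that well and to 1.46 with Ct 40.

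Few markers of other cell types could be tested. In at least 1 sample, 7 of 8 leukocyte, 2 of 2 smooth muscle and 9 of 16 epithelial and kidney tubule markers were detected, against 187 of all 750 assays. For erythroid, striated muscle and neural markers the counts were 0 of 3, 2 of 6 and 1 of 8. Leukocyte markers had a median of 0.23 and a mean of -0.26 over 3 tested members, with a camera adjusted p of 0.630. Their median turned to -1.45, with 3 of 5 members lower, when values not detected were set to Ct 35. The 3 tested members, detected in all mice, kept their values, and -1.45 is the value of miR-146a. This miRNA and miR-146b were added by that setting, each detected in 3 of 4 sham and 1 of 4 ischemia/reperfusion mice. They entered through the sham group alone, so the turn of the median is no sign of a change in the tested markers. miR-223 (0.63 ± 1.00) and miR-155 (0.23 ± 0.66) were higher against the deposited reference and lower without normalization, at -0.76 and -1.16, and miR-150 was at -1.62 ± 2.00. Epithelial and kidney tubule markers were lower in 3 of 3 tested members, miR-30a (-0.22 ± 0.86), miR-30b (-0.79 ± 0.68) and miR-30c (-0.24 ± 0.57), while camera placed the list on the higher side of the other miRNAs (adjusted p = 0.909). Against the mean of the miRNAs detected in all samples, miR-30a and miR-30c were higher, at 0.086 and 0.067. The median of that list moved from -0.24 to -0.79, with 7 of 7 members lower, when values not detected were set to Ct 35. The 3 tested members, detected in all mice, kept their values. The added members, miR-30d, miR-30e, miR-203 and miR-204, were detected in 3 of 4 sham and at most 2 of 4 ischemia/reperfusion mice. They entered through the sham group alone, so their lower values were largely fixed by the filter and carry no support. Of the smooth muscle markers, only miR-145 was tested, so adjusting over the list alone left its unadjusted limma p of 0.0347. Erythroid, striated muscle and neural markers had 0 tested members. In total 0 of the 10 lists with at least 3 tested members passed the camera threshold, and fry, run on 7 of them, gave 0. By camera, 1 list, the fibroblast and mesenchymal markers, had an unadjusted p under 0.05 at the preset correlation, but not at the estimated one.

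miR-146a, a miRNA of inflammatory signalling, was detected in 3 of 4 sham mice and 1 of 4 ischemia/reperfusion mice and was outside the main test. With values not detected set to Ct 35 it was at -1.45 ± 0.63 (SE, n = 4 per group), with an unadjusted limma p of 0.0470 and an adjusted limma p of 0.260. The tubule miRNA miR-192 was detected in 1 of 4 sham mice, at Ct 29.8, and in 0 of 4 ischemia/reperfusion mice. Another listed tubule marker, miR-194, chosen after its values were seen, was detected in sham mice 3 and 4, at Ct 20.5 and 23.7. It was detected in 0 of 4 ischemia/reperfusion mice. Of the 54 miRNAs detected in all samples, those with the lowest mean Ct were miR-1897-5p (18.1), miR-673 (18.5) and miR-1937b (19.6). Their log2 differences were -0.62 ± 4.43, 1.07 ± 2.57 and -1.18 ± 0.87 (SE, n = 4 per group). miR-1897-5p spread over 20.1 cycles among the ischemia/reperfusion mice.

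**Figure D3:**
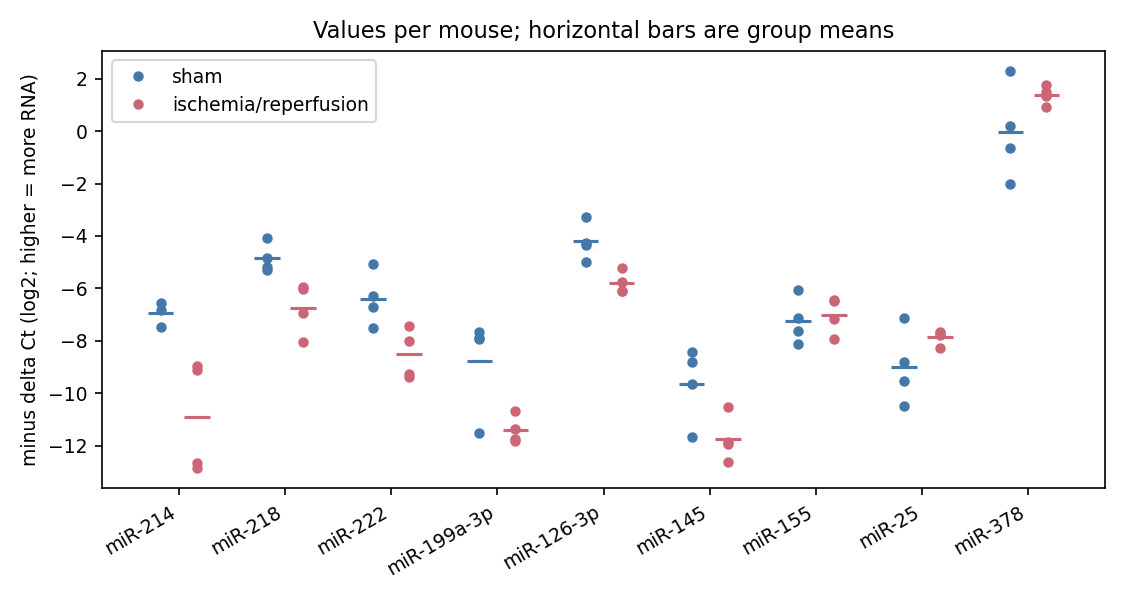
Minus delta Ct (vertical axis, log2 scale, higher is more RNA) per mouse for 9 miRNAs, with sham in blue, ischemia/reperfusion in red and horizontal bars at the group means. miR-199a-3p of sham mouse 2 lies at -11.53, below the other sham mice.

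Detection was also compared for all 750 assays. An assay detected in 3 or 4 of 4 sham mice and in 0 or 1 of 4 ischemia/reperfusion mice was found 25 times, and the reverse 2 times. The reverse assays, miR-212 and miR-101a, were chosen after their values were seen. No assay was detected in 4 of 4 mice of 1 group and 0 of 4 of the other. With 4 against 4 mice, only that pattern can give a Fisher's exact p under 0.05. The test, run on the 133 assays detected in 1 to 7 samples, therefore gave 0 at an adjusted or an unadjusted p under 0.05 (smallest p reached 0.143). Without sham mouse 2, 9 assays were detected in all remaining mice of 1 group and in none of the other, among them miR-221, miR-28 and miR-30e, picked after their values were seen.

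hsa-miR-421, also chosen after its values were seen, was detected in 4 of 4 sham mice, at a mean Ct of 28.4 ± 0.572 (SD, n = 4). It was detected in 1 of 4 ischemia/reperfusion mice, where the mean Ct was 35.7 ± 1.39 (SD, n = 4). It was outside the main test. With values not detected set to Ct 35 it was the only miRNA of 114 past the limma threshold (log2 difference -5.29 ± 0.81, adjusted p = 0.0145). Without sham mouse 2 that count was 6, with miR-15b, miR-199a-3p, miR-28, miR-376c and miR-379 also lower. The adjusted p of hsa-miR-421 ranged from 0.00437 to 0.0705 when each mouse was left out, above 0.05 without sham mouse 1 (0.0642), ischemia/reperfusion mouse 1 (0.0694) or ischemia/reperfusion mouse 4 (0.0705). With the control assays as reference it was 0.110, and with mouse number as a block it was 0.104. The exact permutation test gave an adjusted p of 0.271 from an unadjusted p of 0.0286, the smallest that 4 against 4 samples allow. At that limit a single miRNA among 114 could not pass adjustment, so the exact test cannot decide this call. A second assay of that name, rno-miR-421 on the other card, had a Ct in 0 of 8 samples.

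**Figure D4:**
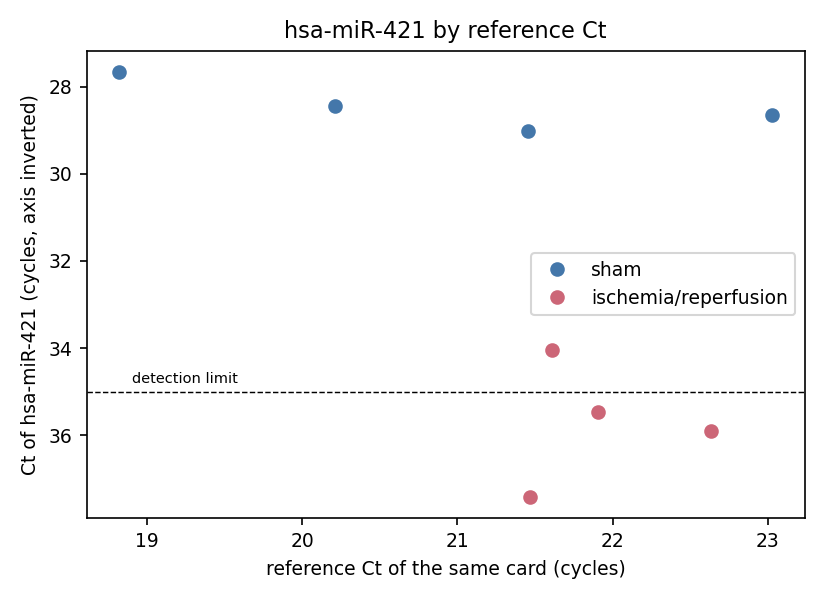
Ct of hsa-miR-421 (vertical axis, cycles, inverted) against the reference Ct of the same card (horizontal axis, cycles), 1 point per mouse. The sham mice lie between 27.7 and 29.0 and the ischemia/reperfusion mice between 34.0 and 37.4; the dashed line is the detection limit of 35.

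The control assays and the reference give the background of these comparisons. The reference Ct was 1.39 cycles higher after ischemia/reperfusion on the first card and 1.02 cycles higher on the second, with an exact permutation p of 0.286 and 0.314. The Ct of snoRNA202 was 24.2 ± 1.94 in sham and 24.9 ± 0.674 after ischemia/reperfusion (SD, n = 4 per group). The Ct of snoRNA135 on the first card was 29.1 ± 2.29 and 30.7 ± 1.40, and that of Y1 was 31.2 ± 3.72 and 32.9 ± 1.44 (SD, n = 4 per group). The snoRNA135 assay on the second card was at 34.1 ± 2.92 (n = 4) and 35.3 ± 2.43 (n = 3). The Y1 assay of the second card and the plant control miR159a on both cards had no Ct. The mean Ct of the 54 miRNAs detected in all samples was 26.3 ± 1.54 in sham and 28.0 ± 0.214 after ischemia/reperfusion (SD, n = 4 per group; exact permutation p = 0.143). None of these 7 differences passed Benjamini-Hochberg adjustment, and the lowest adjusted p was 0.550.

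The authors' deposited table gives a fold change for 150 assays. It includes 9 assays in which 13 wells without a Ct had entered as Ct 0, and those named next were picked after their values were seen. For miR-130a the authors' deposited table gives a fold of 123472. With those wells left out the fold was 1.22, from 4 sham and 2 ischemia/reperfusion wells. For miR-29b the authors' deposited table gives 8.95e-05, against 3.03 without the well. The latter rests on 1 sham and 2 ischemia/reperfusion wells, so it is no estimate of a change. Leaving out these wells turned the direction of 7 of the 9 assays, including miR-193b, miR-20a, miR-224 and miR-484. In miR-484 the authors' deposited table gives a fold of 63.8, and the log2 difference without the well was -2.39. Of the 72 miRNAs tested here, 70 had the same direction in the authors' deposited table.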

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

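The tests of RNA input, the deposited reference, flat Ct values and hsa-miR-421 were chosen after these results were seen. Of 88 groups of 4 samples, 5 had a sample far from the other 3, and chance gives about 4.4. miR-199a-3p in sham mouse 2 was at -11.53 on the minus delta Ct scale, the other sham mice lying between -7.92 and -7.67. miR-30c in sham mouse 1 was at -2.19, with the others between -3.53 and -3.37. Ischemia/reperfusion mouse 4 was low for miR-16, at -12.06, and for miR-152, at -11.71. Ischemia/reperfusion mouse 1 was at -12.16 for miR-1897-5p, while the others lay between 7.10 and 9.10.

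Fewer assays were detected after ischemia/reperfusion and most tested miRNAs had lower values. Lower RNA input is a candidate explanation for the detection part. With the mean reference Ct of each sample in a linear model, the difference of -37 assays became -14.9 (exact permutation p of the residuals 0.114). The raw difference had an exact permutation p of 0.143, so a remaining difference was no less supported after adjustment. A shift of the deposited reference cannot be told apart from a lower miRNA level, because the median of common miRNAs differed by -0.55 against that reference and by -0.70 against the control assays (exact permutation p = 0.314), with wide spread between mice. A change in these cells after ischemia/reperfusion stays open and untested.

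Some miRNAs had higher mean values after ischemia/reperfusion while their Ct hardly moved between mice. Signal that does not follow RNA input is a candidate explanation, since a flat Ct turns into a higher value where the reference Ct is higher. Across the 72 assays, which are not independent replicates, the slope of Ct on the reference Ct within groups had a Spearman rho of -0.36 with the log2 difference (permutation p = 0.00227). A rise stays open. The 4 assays with a positive difference and an unadjusted limma p under 0.3 had a median raw Ct difference of -0.065 cycles. The values were -0.39 for hsa-miR-378, 0.25 for miR-25 and 0.30 for miR-34c#. miR-1894-3p was at -4.60 with ischemia/reperfusion mouse 2 left out, and its Ct was not flat (17.1 to 35.8 over all mice). The slopes of the 4 assays were not clearly lower than those of the other assays (permutation p = 0.309).

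hsa-miR-421 was lower after ischemia/reperfusion in the settings that could test it. Lower RNA input as the whole cause is argued against by the gap of 5.01 cycles between the groups, wider than the reference range of 4.21 cycles. The limit of detection as the whole cause is argued against by the log2 difference of -6.24 with every Ct kept (n = 4 per group). At a limit of Ct 38 its SE was 0.985 and its adjusted limma p 0.0171. With no limit and 210 assays tested its SE was 1.11 and its adjusted limma p 0.0884, which did not pass. Signal in the sham mice that does not follow RNA input cannot be told apart from a real level, since the slope of their Ct on the reference Ct was 0.25 with a 95% interval from -0.37 to 0.86. With values not detected set to Ct 35, 4 of the 35 splits of the 8 samples, the real one included, gave at least as many calls (real 1, highest other 8). Chance is therefore not excluded. The split with 8 calls differed from the real grouping only by exchanging sham mouse 2 and ischemia/reperfusion mouse 2. The absence of any Ct for rno-miR-421 leaves the identity of the signal open, as the assay sequences were not compared.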

How the results depend on the processing

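The settings that keep the Ct 0 wells, leave out assays with wide Ct spread, or combine Ct 35 with another reference were chosen after seeing the data. Changed miRNAs stayed at 0 with the other references, no normalization, Ct 32, undetermined wells at Ct 40 and detection in all 8 samples. They also stayed at 0 with trend and robust moderation, the Ct 0 wells kept and the wide assays left out. The exact test gave 0 too, but it could pass only if many miRNAs reached its smallest possible p together. The count was 1, hsa-miR-421, at a limit of Ct 38, with Ct 35 for values not detected, and with that and the global mean, which admit assays that the main test left out; with that and the control assays or mouse number as a block it was 0. With Ct 35 and without sham mouse 2 it was 6. Leaving out each mouse gave 0 to 1 changed miRNAs and 0 lists, and lists past the threshold were 0 in every setting run. U6 as reference was not run because no U6 assay was used here. With mouse number as a replicate block the count was 0, and 0 samples correlated best with their own number (correlations -0.20 to 0.16), so the numbers were not taken as pairs.

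Assays detected in 1 group only numbered 0, 1 at Ct 32 (hsa-miR-421), and 0 to 9 when each mouse was left out: 9 without sham mouse 2, 2 without ischemia/reperfusion mouse 1 (miR-140 and miR-34b-3p, chosen after their values were seen) and 2 without mouse 3 (hsa-miR-421 and miR-212). The difference in detected assays ranged from -54.25 to -24.9, with an exact permutation p of 0.0286 without sham mouse 2. The mean Ct difference of common miRNAs ranged from 1.20 to 2.41, with an unadjusted exact permutation p of 0.0286 without sham mouse 2, and that of snoRNA202 from -0.086 to 1.42, below 0 without sham mouse 4. The cause was not tested.

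Of the 44 named and tested miRNAs, 32 kept their direction in every setting that tested them, and 30 turned or moved by over 1.5 times when 1 mouse was left out. Against the global mean, miR-30c (0.067), miR-30a (0.086) and miR-1897-5p (0.051) turned, with the same values when values not detected were set to Ct 35. Without normalization, miR-25 (-0.25), miR-363 (-0.15), miR-106b (-0.49), miR-223 (-0.76) and miR-155 (-1.16) turned. miR-1897-5p was 4.44 at Ct 32. With undetermined wells at Ct 40, miR-127 was 1.46 and miR-100 0.46. With Ct 35, miR-127 was 0.21, and 0.51 and 0.14 with the global mean and the control assays. miR-484 was 5.99 with the Ct 0 wells kept. Leaving out each mouse, miR-155 ranged from -0.074 to 0.62, miR-30c from -0.43 to 0.086, miR-30a from -0.91 to 0.22, miR-673 from -0.82 to 2.66 and miR-1897-5p from -2.65 to 4.44. The cause was not tested.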

Other observations

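The tests of the counts of adjusted calls and lists were chosen after the result was seen. Some assays gave very uneven Ct values. The Ct of rno-miR-190b ranged from 14.5 to 39.3, with 3 sham and 2 ischemia/reperfusion wells below 18 cycles, and that of miR-1897-5p ranged from 13.5 to 33.6. miR-21 and miR-27b also spread widely in the sham mice, by 11.3 and 11.7 cycles, while the reference Ct spread by 4.51 and 4.21 cycles on the first and second card. These miRNAs were chosen after their values were seen, as were those in the next paragraph.

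Both assays for miR-223 had higher mean values after ischemia/reperfusion, hsa-miR-223 at 1.15 ± 1.13 and mmu-miR-223 at 0.63 ± 1.00 (SE, n = 4 per group), while mmu-miR-223 was lower without normalization. Both assays for miR-146b were detected in 3 of 4 sham mice, and in 1 and 2 of 4 ischemia/reperfusion mice.

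Chance was not excluded for the number of miRNAs at an unadjusted p under 0.05. The real grouping gave 10 miRNAs at an unadjusted limma p under 0.05. At least as many were given by 5 of the 35 splits of the samples, the real one included, with 15 as the highest of the other splits. Apart from the real one, these 5 all joined sham mice 1, 3 and 4 with 1 ischemia/reperfusion mouse. They differ from the real grouping only by exchanging sham mouse 2, so the comparison cannot settle whether chance gave the count. For the adjusted count the real value was 0 and the highest other 1, and for lists past the threshold the real value was 0 and the highest other 2. A real value of 0 is reached by all 35 splits whatever the data, so these counts carry no information on chance.

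The hypothesis that miRNAs from a shared primary transcript have similar differences was tested on neighbours within 10 kb. The 12 pairs had a median absolute difference of 1.46 in log2 difference, against 1.39 for permuted pairs (one-sided permutation p = 0.561), so this test does not bear out the hypothesis and leaves it open. miR-106b and miR-25 lay at 0.90 and 1.14, while miR-92a and miR-363 lay at -0.93 and 1.24.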
